A study of Rattus norvegicus with 6 samples.

How the data were processed

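The series holds RNA-seq of sorted CD11b+CD163+ cells from rat brain, with 3 libraries of the MCAO group and 3 of the sham group, assigned from the sample titles. Per the labels' protocols the libraries were strand-specific, made from poly(A) RNA with a dUTP kit, and the 3 libraries of each group are biological replicates. The labels do not say whether one library stands for one animal or several, so p-values measure the spread between these libraries. The submitters' processing notes name bcl2fastq, TopHat2, RSEM and the genome build rn5, without versions, settings or an annotation release, and the counting strand is not given in the sources used here.

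Each library has one table of 30404 Ensembl transcripts. Per the file headers, the authors deposited RSEM's expected counts, which are estimated counts not scaled for depth, and RSEM's TPM, scaled by effective length to the same sum in each library (1000000.39 in MCAO replicate 3, the largest). The authors also deposited FPKM, which was not used here, and RSEM's isoform percent. The deposited percent values were only 0 or 100, so RSEM treated each transcript as a gene of its own and did not sum the transcripts of one gene. Between 12.0% and 13.6% of all expected counts in a library, counts of 0 included, were not whole numbers, as arises when RSEM divides reads among similar transcripts. Of the tested transcripts, 27.0% had a fractional count in some library. Among tested transcripts, 107 in 53 sets had expected counts identical to those of another tested transcript in every library.

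No table used here pairs the transcript identifiers with gene names. The RefSeq table of rat genes has a column for Ensembl identifiers, but 0 of its cells are filled, so no match was possible. No genome of the authors' build was used, so no coordinates are given. The levels of the sort markers and the 33 gene lists fixed beforehand could not be computed. The rule for transcripts to name was fixed before the data were examined, as were the tests and the alternatives except where stated. It took the 10 largest positive and 10 largest negative log2 fold changes among transcripts past the threshold, with a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and a gene symbol. The condition on symbols had to be dropped, and only 2 identifiers per direction are printed, with ties taken in order of identifier.

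Expected counts were rounded to whole numbers. Transcripts were kept by edgeR's filterByExpr, which left 13471 and from 99.7% to 99.9% of the counts of each library. Libraries were scaled by TMM, and the groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, all 6 libraries, group as the only term) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all tested transcripts, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 21.3%. Depth limits detection at a floor of 3 counts per library, which is 0.24 to 0.33 CPM. This floor covers counting error only, since PCR reads without molecular identifiers are not independent molecules.

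Alternatives were RLE scaling, library totals without a composition factor, DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1) on log2(TPM + 1) and log2(TPM + 0.1). Further alternatives were no low-count filter, a filter of at least 5 CPM in at least 3 libraries, a required change beyond a log2 fold of 1, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were limma-trend on log2(TMM-scaled CPM + 1), a fit on transcripts with whole counts only, thinning of all libraries to the smallest total, and removal of each library's lowess trend on transcript length (span 0.4).

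The fits were tested on simulated data for the MCAO against sham comparison with 13471 transcripts, 200 of them changed. edgeR's test recovered 12% of the 50 transcripts changed 1.5-fold, 54% of those changed 2-fold, 84% of those changed 4-fold and 90% of those changed 8-fold. Of its 128 calls, 8 (6.25%) were false, against 44 of 193 (22.8%) for DESeq2. With a length trend simulated in the MCAO libraries, edgeR made 870 false calls without the length correction and 9 with it. That trend rose with length, while fold changes in the real data fell with it, and its size was not matched to the real trend. The result therefore does not show how the correction acts on the real trend. In the real data 43.0% of tested transcripts were called, far more than the 200 changed here. The adjusted threshold is less strict on raw p when more transcripts change. The recovered and false shares therefore describe the simulated setting and do not carry over to the real data.

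No batch is given in the labels. Length minus effective length, which follows the mean fragment length that RSEM used, was 168 bases in MCAO replicate 3 and 162 bases in sham replicate 3, and 174 to 181 bases in the other 4 libraries. Group means were 176 ± 6.79 bases after MCAO and 170.2 ± 7.36 bases after sham (SD, n = 3, exact two-sided permutation p = 0.5). No 2 libraries held the same values, and the common coefficient of variation of any pair within a group was at least 17.1%, so all 6 were counted as separate.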

Results

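Poly(A) RNA of CD11b+CD163+ cells from the brains of adult Wistar rats was sequenced in 6 libraries. CD11b is an integrin subunit of myeloid cells, and CD163 is the haemoglobin-haptoglobin scavenger receptor used here to sort macrophages of the brain's vessels and meninges. The MCAO group held 3 libraries from rats whose middle cerebral artery had been occluded for 90 min and then reperfused, and the sham group held 3 libraries from rats given the control operation. The time between the operation and the sort is not given in the sources used here. Expected counts per library summed to 12630809, 9702976 and 12686850 in MCAO replicates 1, 2 and 3, and to 8896485, 9700222 and 10566082 in sham replicates 1, 2 and 3. A count above 0 was listed for 17232 ± 167 transcripts after MCAO and for 16916 ± 273 after sham (SD, n = 3 each). That difference gave p = 0.2 in an exact two-sided permutation test, whose smallest possible p for 3 against 3 libraries is 0.1.

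The values belong to Ensembl rat transcripts, each listed by its transcript identifier and length. The deposited tables pair none of the 30404 identifiers with a gene name or a genomic position. The RefSeq gene table used here carries no Ensembl identifiers (0 filled cells), so it could not supply names either. Cd163 and Itgam, which encode the sorted proteins, and the lists of cell type and pathway genes chosen beforehand were therefore not analysed here. The results below describe transcripts by abundance, length and identifier, and a gene with several transcripts can enter a count more than once.

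The first question was whether the libraries grouped by operation. Between libraries of the same group, log2 CPM of the 13471 tested transcripts correlated with Pearson's r of 0.966 to 0.969 after MCAO and of 0.935 to 0.948 after sham. Between libraries of different groups, r lay between 0.872 and 0.915. These correlations are across transcripts, which are not independent replicates. The first principal component of the 500 most variable transcripts held 47.8% of their variance. The 3 MCAO libraries scored 27.2 to 37.3 on it and the 3 sham libraries -40.3 to -26.1. The second component held 18.5% and mainly set sham replicate 3, at 34.2, apart from sham replicate 2, at -33.4.

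**Figure D1:**
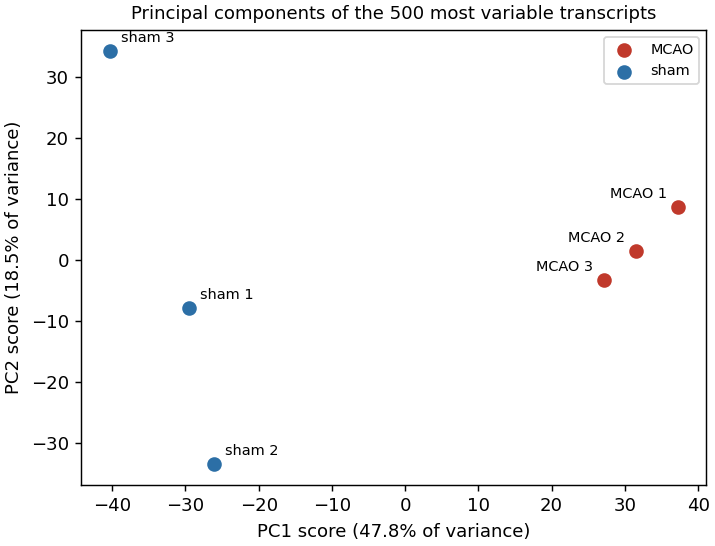
Scores of the 6 libraries on the first 2 principal components (PC1 and PC2, axes in score units of log2 CPM, with the share of variance in percent) of the 500 most variable transcripts. Each point is one library, coloured by group: the MCAO libraries lie at 27.2 to 37.3 on PC1 and the sham libraries at -40.3 to -26.1.

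The study's comparison was between CD11b+CD163+ cells after MCAO and after sham. After MCAO, 3050 transcripts were higher and 2747 were lower at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 per group). Together these 5797 transcripts made up 43.0% of those tested, and the other 7674 did not pass the threshold. Among the higher transcripts the median change was 0.75 on the log2 scale, and among the lower ones it was 0.81 in size. A change of at least 2-fold was fitted for 1005 of the higher and 1098 of the lower transcripts. A change of at least 4-fold was fitted for 333 higher and 302 lower transcripts, and one of at least 8-fold for 113 higher and 86 lower ones. These counts depended on the method: at least 8-fold, 167 were higher and 174 lower with DESeq2, 66 and 34 with a filter of 5 CPM, 51 and 14 with limma on log2(TMM-scaled CPM + 1), and 42 and 13 with limma on log2(TPM + 1). At least 4-fold, 215 were higher and 119 lower with the filter of 5 CPM, 194 and 101 with limma on log2(TMM-scaled CPM + 1), and 137 and 90 with limma on log2(TPM + 1). Counts in both directions also moved when a single library was left out. Without sham replicate 2, 513 were at least 4-fold and 172 at least 8-fold lower, and without MCAO replicate 3, 135 were at least 8-fold lower. The count at least 8-fold higher ran from 107 without MCAO replicate 1 to 157 without sham replicate 1. The count at least 2-fold lower was 709 without MCAO replicate 1, 783 without MCAO replicate 2 and 1253 without sham replicate 2. Such fits have fewer libraries and less power, so a lower count does not single out the library left out. Over all 13471 tested transcripts, changed or not, the 3 libraries of one group all lay above the 3 of the other for 7659 (56.9%), against 10% expected by chance. When the test itself required a change beyond 2-fold, 325 transcripts were higher and 127 lower (edgeR's glmTreat).

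The split between directions depended on the scaling. With limma on log2(TPM + 1), 2315 transcripts were higher and 3585 lower, so that the higher ones made up 39.2% of the changed transcripts against 52.6% with TMM-scaled counts. The same limma test on log2(TMM-scaled CPM + 1), added after seeing the data, gave 3110 higher and 2796 lower transcripts (52.7% higher), so the change of test did not move the split. With edgeR on library totals alone, 2609 were higher and 3220 lower (44.8% higher). With each library's trend on transcript length removed, 3465 were higher and 2245 lower (60.7% higher). That fit also corrected each library's level again on top of TMM, and its median log2 fold change was 0.068. Its split is therefore not read as an effect of length. The median log2 fold change of all tested transcripts lay 0.12 lower on the TPM scale, at -0.12 against -0.0020. On that scale, 2270 of the 3050 higher and 2687 of the 2747 lower transcripts were called again. Without MCAO replicate 1, the count of lower transcripts was 1817.

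**Figure D2:**
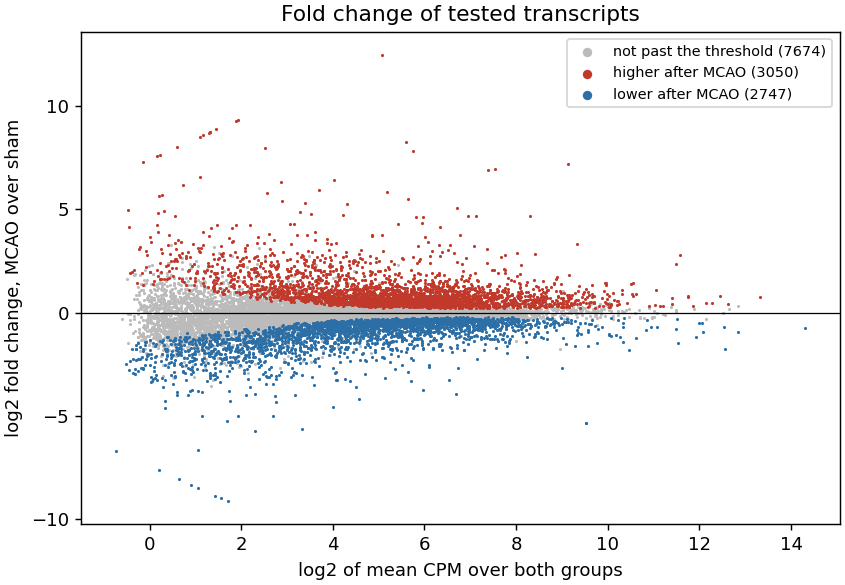
Log2 fold change of MCAO over sham (y axis) against the log2 of the mean CPM over both groups (x axis) for the 13471 tested transcripts, one point each. Red points are the 3050 transcripts higher after MCAO and blue points the 2747 lower at an adjusted p under 0.05 by edgeR. Grey points are the 7674 that did not pass.

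Among transcripts with at least 10 CPM in one group, the 2 largest fitted increases were of transcripts with at most 7 counts in any sham library. ENSRNOT00000075989 (1436 bases), which ranked first by its fitted fold change, was measured at 67.8 ± 20.7 CPM after MCAO (SD, n = 3), from 583 to 1078 counts per library. It had 0 counts in each of the 3 sham libraries. Its mean level after MCAO was 224-fold above a floor of 3 counts per sham library, and its adjusted p was 0.00041 by edgeR's quasi-likelihood test. The lowest MCAO library stood at 47.1 CPM. Not all counts of this transcript were whole numbers, as arises when RSEM divides reads among similar transcripts. Its 0 counts after sham may depend on that division, which the floor does not cover. Its rank rests on a fitted fold over 0 counts, and on the log2(TPM + 1) scale it came after the next one (6.05 against 6.15). The next, ENSRNOT00000017911 (1441 bases), stood at 96.5 ± 35.1 CPM after MCAO and 0.32 ± 0.38 CPM after sham, where it had 1 to 7 counts per library. Its log2 fold change was 8.26 ± 0.52 (SE), with an adjusted p of 0.00022 by edgeR. The ratio of summed counts per library size, 3331 after MCAO against 9 after sham, was 324 (exact binomial 95% interval 171 to 710, which covers counting alone and not differences between libraries). Sham replicate 1 held 7 of these 9 counts, and the fitted log2 fold change without it, 9.80, rests on 1 count in each remaining sham library, so no larger fold is read from it. The log2(TPM + 1) scale understates changes of low transcripts. The 10 most increased transcripts with at least 10 CPM in the higher group each had a log2 fold change of 5.96 or more, and 1 of them had 0 counts in every sham library.

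Among transcripts with at least 10 CPM in one group, the strongest decreases were smaller than the strongest increases. ENSRNOT00000011168 (842 bases) stood at 0.39 ± 0.20 CPM after MCAO, from 2 to 6 counts per library, and at 19.7 ± 4.80 CPM after sham (SD, n = 3). Its log2 fold change was -5.63 ± 0.39 (SE), with an adjusted p of 0.00027 by edgeR. It was -4.57 on the log2(TPM + 1) scale and -3.87 on the log2(TMM-scaled CPM + 1) scale. ENSRNOT00000049667 (1926 bases) was abundant after sham, at 1434 ± 548 CPM, and stood at 35.4 ± 28.2 CPM after MCAO. Its log2 fold change was -5.33 ± 0.63 (SE), with an adjusted p of 0.0010 by edgeR. It was -6.19 without MCAO replicate 3, which held 67.8 CPM against 21.9 and 16.5 in replicates 1 and 2. With all libraries, ENSRNOT00000049667 changed by -5.60 on the log2(TPM + 1) scale and by -5.48 on the log2(TMM-scaled CPM + 1) scale. On both scales its decrease was the larger of the 2. Another transcript of the same length held identical counts in every library, so its reads could not be assigned to one of the 2, and its value is uncertain as a level of either. The 10 most decreased transcripts with at least 10 CPM in the higher group had log2 fold changes between -5.63 and -3.75.

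Few transcripts were detected in one group alone. There were 14 transcripts with 0 counts in all 3 sham libraries and at least 10 counts in each MCAO library, and 7 with the opposite pattern. In the 9 other divisions of the 6 libraries into 3 and 3, which mix the operations, either number was at most 6. With any one library left out, which loosens the condition, the numbers were 21 to 34 and 13 to 16. MCAO libraries held 11673545 ± 1706793 counts on average and sham libraries 9720930 ± 834991 (SD, n = 3), so a count of 0 was less informative in sham libraries.

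The most abundant transcripts of these cells also differed. The transcript with the highest mean TPM (1144 bases) took 1.94 ± 0.25% of all TPM after MCAO and 3.62 ± 0.48% after sham (SD, n = 3). Its log2 fold change was -0.76 ± 0.13 (SE), with an adjusted p of 0.0035 by edgeR. The second (723 bases) took 1.15 ± 0.29% after MCAO and 2.39 ± 0.23% after sham, with a log2 fold change of -0.93 ± 0.18 (SE) and an adjusted p of 0.0063 by edgeR. Of the 100 most abundant transcripts, 42 were higher, 13 were lower and 45 did not pass the threshold. On the TPM scale, 23 of these 100 were higher and 14 lower. Together they held 37.7 ± 0.41% of TPM after MCAO and 38.4 ± 0.79% after sham.

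The share of changed transcripts varied with abundance. Of the 4312 transcripts with a mean of 1 to under 10 CPM, 474 were higher and 761 lower. Of the 1872 with a mean of 100 to under 1000 CPM, 680 were higher and 452 lower, a changed share of 60.5% against 28.6% in the less abundant class. The test has more power at higher counts, so this difference is not read as a more frequent response of abundant transcripts. The direction of the split among the more abundant class turned with limma on log2(TPM + 1), where 500 were higher and 603 lower. It did not turn with the same limma test on log2(TMM-scaled CPM + 1), at 690 and 464, or with edgeR on library totals, at 583 and 540. For the 7027 transcripts of 10 to under 100 CPM, 1843 were higher and 1472 lower with TMM. That split turned with library totals, at 1553 and 1750, and with limma on log2(TPM + 1), at 1302 and 1926. Among transcripts of 1 to under 10 CPM, lower calls outnumbered higher ones under each scaling tried (TMM, RLE, library totals and TPM).

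The split between directions also varied with transcript length. Among the 1433 tested transcripts of 501 to 1000 bases, 381 were higher and 159 lower. Among the 1989 transcripts over 4000 bases, 381 were higher and 544 lower. The median log2 fold change was 0.17 for transcripts of up to 500 bases and -0.12 for those over 4000 bases. The changed share in both directions together rose from 24.8% to 46.5% between these classes. Counts, and so power, were not matched between length classes, so the rise of a share with length is not read as a more frequent response. Both classes up to 1000 bases had more higher than lower calls, and both classes over 2000 bases had more lower than higher calls, under each of the 4 scalings. Between 1001 and 2000 bases, 1099 were higher and 836 lower with TMM, but 874 were higher and 1203 lower on the TPM scale, and 942 and 989 with library totals alone.

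**Figure D3:**
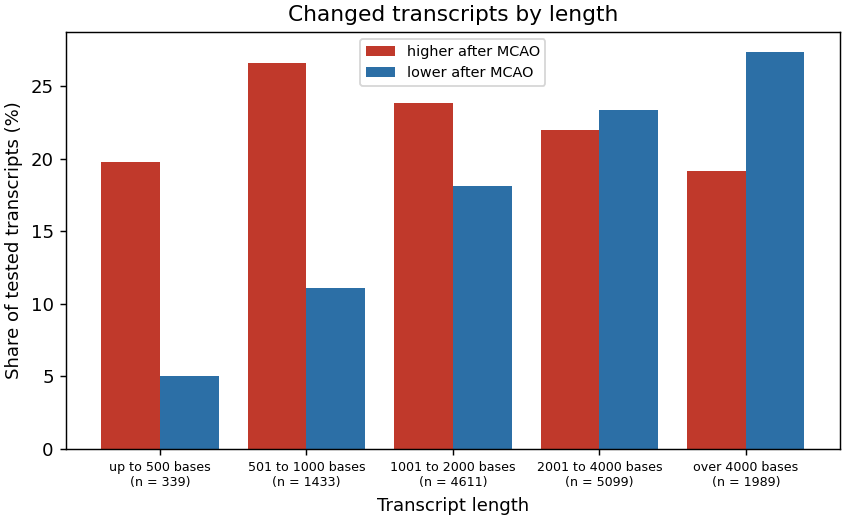
Share of tested transcripts, in percent, that were higher (red bars) or lower (blue bars) after MCAO at an adjusted p under 0.05 by edgeR, for 5 classes of transcript length in bases, with the number tested in each class. The lower share runs from 5.01% in the shortest class to 27.4% in the longest, while the higher share lies between 19.2% and 26.6%. Power was not matched between the classes.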

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

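The total counts of higher and of lower transcripts stayed, over 20 alternatives, within 1.5 times the reported values except in 2 cases. Requiring a change beyond 2-fold (glmTreat) left 325 higher and 127 lower transcripts. Leaving out each library in turn gave 1817 to 2485 lower transcripts, the lowest without MCAO replicate 1, and 2331 to 2780 higher ones; these fits have fewer samples. Counts at least 8-fold ranged from 42 to 173 higher and from 13 to 174 lower over all alternatives, against 113 and 86 reported. With glmTreat they moved less than the totals, to 91 higher and 51 lower. Of the 5797 changed transcripts, 4043 to 4771 were called again when one library was left out, 5176 with DESeq2, 5597 with limma-voom, 5356 with library totals alone and 4957 with limma on log2(TPM + 1). None changed sign under any alternative, but scalings that shift all transcripts nearly alike, and glmTreat, which reuses the same fold changes, could hardly turn one. Leaving out 1 library could hardly do so either where the groups' libraries did not overlap, which held for 5757 of the 5797. The counts of calls with the numbers of the titles as a replicate block were 2787 higher and 2404 lower. Same-numbered libraries did not deviate together (correlations of deviations from the group mean 0.04, 0.07 and -0.02 for numbers 1, 2 and 3), and not every library correlated best with its own number. The labels do not tie the numbers to an animal or day, so the block was not used. Both libraries numbered 3 had the lowest length minus effective length of their group, 168 bases in MCAO and 162 bases in sham. A shared preparation by number is therefore not excluded. The gap between the lowest correlation within groups and the highest between groups was 0.019 in the main setting. It was 0.00089 without a low-count filter, 0.048 with the filter of 5 CPM, and 0.019 to 0.040 with one library left out, the highest without sham replicate 2. The 4 named transcripts stayed past the threshold in every alternative that tested them, with adjusted p at most 0.0062; those with fractional counts were not tested in the fit on whole counts. The sort marker levels and the gene lists were not run under any setting, for want of gene names. Depth limits what can be said of transcripts under about 1 CPM, of which only 158 were tested.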

Other observations

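Among the tests below, those of the spread between sham libraries by depth and by single libraries, and those of the length trend, were chosen after the patterns had been seen. The fits with length trends removed, with thinned libraries and on whole counts were likewise chosen after the data had been seen.

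Libraries within a group differed in how far they carried the strong changes. Of the 86 transcripts at least 8-fold lower after MCAO, 64 (74.4%) were lowest in sham replicate 2 among the sham libraries, against 33.3% for libraries in random order. Of the 113 transcripts at least 8-fold higher, 76 (67.3%) were highest in MCAO replicate 1 among the MCAO libraries. Transcripts are not independent, so these shares describe these libraries only. The set of lower transcripts itself depended on that library, since 172 were at least 8-fold lower without sham replicate 2.

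The number of changed transcripts was weighed against grouping by chance and 3 technical explanations. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave 5797 transcripts, and the highest of the others gave 2. With 10 splits the share cannot fall under 0.05. The other splits also mix MCAO and sham libraries, which puts the difference between operations into the spread within groups. Their low numbers are therefore no measure of what grouping by chance gives. Removing each library's trend on transcript length left 0.985 times as many changed transcripts, with 5191 of the 5797 (89.5%) called again. Thinning all libraries to the smallest total left 0.969 times as many. The thinning argues against depth as the cause of the total count. The total with trends removed cannot weigh length bias, since that fit also moved levels and gained higher calls where lower calls were lost. Of the 2747 lower transcripts, 2203 were called again despite the upward move of the median. That argues against length trends as the source of most lower calls. The fit with trends removed moved the split to 3465 higher and 2245 lower. Its trends were fitted without the composition factor, which was then applied as well, so each library's level was corrected again. The median log2 fold change of all tested transcripts rose from -0.0020 to 0.068. That move of the split therefore cannot be assigned to the length trend. Transcripts with whole counts and no identical partner were changed 1.33 times as often as those with fractional counts (46.1% against 34.6%). The 2 classes were not matched for abundance, which the changed share follows, so this ratio cannot weigh the effect of shared reads. Of the 5797 changed transcripts, 4537 had whole counts and no identical partner. That argues against reads shared between similar transcripts as the source of most calls. The operation itself, and a difference in which cells passed the CD11b+CD163+ gate, stay open; the latter was not tested because no transcript could be assigned to a marker gene.

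Sham libraries varied more among themselves than MCAO libraries. The common biological coefficient of variation was 24.7% over the sham and 18.1% over the MCAO libraries, but the median SD of log2 CPM was 0.18 in both groups. The difference lay in a tail of transcripts: 2269 had an SD over 0.5 in sham libraries and 1555 in MCAO libraries. After thinning, the coefficient was still 1.40 times as large in sham libraries, which argues against depth. Of the transcripts at least 8-fold higher after MCAO, 23.0% were highest in sham replicate 2 among the sham libraries. That set was chosen partly on sham replicate 2, so transcripts raised there tended to drop out. The share therefore cannot decide whether that library held material from MCAO cells. Among the sham libraries, replicate 2 correlated best with each MCAO library on log2 CPM (r of 0.887, 0.900 and 0.915). On log2(TPM + 1) this held for MCAO replicates 2 and 3, but MCAO replicate 1 stood slightly closer to sham replicate 1 (0.9195 against 0.9191). Sham replicate 2 was also lowest for 74.4% of the transcripts at least 8-fold lower, so this explanation stays open. A single aberrant sham library cannot be excluded, since the closest sham pair, replicates 1 and 3, had a coefficient only 1.06 times that of the least similar MCAO pair; a candidate explanation that stays untested is a mix of sorted cells that varied between sham libraries.

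Fold changes fell with transcript length (Spearman's rho -0.11 across transcripts, which are not independent). Relative to the mean of all 6 libraries, the slope of log2 CPM per doubling of length was -0.06 to -0.02 in the 3 MCAO libraries and 0.03 to 0.05 in the 3 sham libraries; only the differences between libraries carry meaning, since centring on that mean sets the opposite signs. The gap between the groups was 1.17 times the largest range within a group, but this measure was chosen after the trend was seen, and 3 libraries separate fully from 3 others in 2 of 20 orderings by chance, so trends that vary between libraries regardless of the operation stay open. The shift of slope per base of fragment length within groups was at most 0.12 times that between groups, which argues against fragment length. RNA integrity and a true difference in the length of the transcripts these cells use stay open as hypotheses, and GC content was not examined because no sequences were used.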
